A study of Mus musculus with 11 samples.

How the data were processed

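Chromatin accessibility was measured by ATAC-seq, which tags open DNA with a transposase, in 11 libraries of CD4 T cells sorted from mouse spleen and lymph node. Per the labels, the libraries form 4 groups: naive (n = 2), Teff (n = 3), anergic (n = 3) and Treg (n = 3). The series also describes RNA-seq, which was not analysed here. Per the series' design text, reads were trimmed with Trimmomatic 0.38.1 and aligned to mm10 with Bowtie2 2.3.3.1 in its very sensitive mode. SAMtools 1.13 sorted the alignments and Genrich 0.5 called peaks per sample, removing PCR duplicates, adjusting for the transposase and leaving out mitochondrial and blacklisted reads, per the same text. DiffBind 2.10.0 then gave 38509 consensus peaks, per the series' design text.

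The deposited table holds 1 signal value per peak and library. The name of the deposited file calls the data raw, yet the values are not whole numbers. Dividing each library's deposited signal values by the smallest value in its column gave whole numbers within 0.01 for 100.0% of values, with a largest deviation of 0.0001. Each column was therefore read as reads per peak times a library factor, the method of which the labels do not state. The smallest value in each library was taken to be 1 read, and 1 read was worth 0.527 (anergic replicate 2) to 2.13 (Treg replicate 2) units of deposited signal. No value was 0, and 17 to 368 peaks per library stood at 1 read, and whether peaks without reads were entered as 1 read is not stated.

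Reads in peaks, recovered in this way, ranged from 14.7 to 68.8 M per library. Starts in the file count from 0 and were raised by 1. Of the peaks, 38441 lay on chromosomes and 68 on unplaced contigs. Each peak on a chromosome was given to the gene with the nearest RefSeq transcription start site (45756 transcripts), measured from the peak's centre. This assignment was computed here, and a peak's gene part can belong to a neighbouring gene, so distances are given. Peaks within 1000 bases of a start site were called promoter peaks (12766) and the others distal (25675).

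The planned test was edgeR on raw counts. Because the deposited values were scaled, limma-trend (limma 3.58.1 in R 4.3.3) was run on log2 of the deposited value plus 1, with all 11 libraries in 1 fit and group as the only term. The filter of edgeR 4.0.16 (filterByExpr, on recovered reads) removed 16 peaks and left 38493. Adjusted p-values are from limma with the Benjamini-Hochberg method over these peaks, with a threshold of 0.05, and errors of log2 fold changes are standard errors. Group values are means of the deposited signal with SD. The labels do not state whether replicates are separate animals, so p-values measure the spread between these samples.

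In simulated reads for anergic against Teff, with the depths and dispersion of the real libraries over 38493 peaks, limma recovered 15 of 71 peaks changed by 1.5-fold (21.1%), 37 of 60 changed by 2-fold (61.7%) and 69 of 69 changed by 4-fold, with 6 unchanged peaks called. For Teff against naive the shares were 28.8%, 41.5% and 92.8%, with 5 unchanged peaks called. The simulations changed far fewer peaks than the real comparisons called. The Benjamini-Hochberg cutoff is stricter when few peaks change, so these shares are not the recovery in the real data. The gene list, motif and regression steps were also tested on simulated data.

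Genes named for each comparison followed a rule fixed before the data were examined. It takes sort markers, among them Cd4, Cd44, Nt5e, Izumo1r, Nrp1, Foxp3 and Il2ra with Batf and Bcl2l11, each by the peak with the smallest adjusted p. It adds the 5 higher and 5 lower peaks with the largest change that have a named gene and no overlap between the libraries of both groups, and up to 3 genes from each gene list. Those largest changes also had to pass, to have an average log2 CPM above a fixed floor and not to lie nearest to a predicted gene. Each gene entered by its largest change only. Rankings of the largest rises and falls hold among peaks that met these terms. Other peaks or genes are marked as chosen after their values were seen.

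There were 20 gene lists, written from general knowledge: sort markers; anergy and negative TCR regulators; inhibitory receptors and exhaustion regulators; Treg signature; naive and quiescence; Tfh; Th1 and cytotoxic; Th2; Th17; AP-1, BATF and IRF factors; NR4A, EGR and NFAT factors; BCL2 family and cell death; adenosine and folate receptor pathway; cytokines and TNF family ligands; migration and tissue residency; B cell markers; myeloid and dendritic markers; CD8, NK and innate-like T markers; erythroid and platelet markers; and housekeeping controls. Of their 390 entries, 388 matched a gene. Lists were tested with fry and with camera (limma), adjusted over all lists and comparisons. Fry tests whether a list's peaks move on balance one way and does not compare the list with other genes. Peaks of 1 gene are not independent. Lists share genes, so their results are not separate findings. Il10, for example, is on the inhibitory receptor, Th2 and cytokine lists, and Tnfsf8 on the Tfh and cytokine lists.

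Promoter share was compared by Fisher's exact test (two-sided), changed against unchanged peaks. For 16 motif patterns, logistic regression over 25666 distal peaks compared peaks that changed with those that did not, adjusted for log2 peak width and GC content, with 95% intervals. Both treat peaks as independent. Similarity of libraries was Pearson's r across peaks of log2 CPM with a prior count of 2, and principal components used the 2000 most variable peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used beside R.

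Alternatives were DESeq2 1.42.0 size factors and its Wald test, total reads in peaks, loess offsets, filters, a stricter threshold, a replicate block, fits of only the groups compared and leaving out each library. The edgeR quasi-likelihood test on recovered reads, TMM factors, a pseudocount of 8, thinned reads and leaving out the 3 shallowest libraries were added after the data were seen. Ranges of log2 fold changes run over the alternatives and are given where any of them moved the fold by over 1.5 times.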

Results

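Accessible chromatin was profiled in CD4 T cells that differ in experience of antigen. Naive cells were CD44 low. Teff cells were CD44 high, FOXP3 negative and low for CD73 and FR4. Anergic cells were CD44 high, FOXP3 negative, high for CD73 and FR4 and positive for NRP1, a phenotype of T cells that no longer respond to antigen. Treg cells were FOXP3 and CD25 positive. The title names BATF, a transcription factor of the AP-1 family, and BIM, a protein encoded by Bcl2l11 that promotes cell death. Reads in peaks were 45.7 and 48.1 M in the naive libraries and 50.9, 44.3 and 20.9 M in the Teff libraries. They were 21.5, 68.8 and 55 M in the anergic libraries and 29.7, 14.7 and 27.4 M in the Treg libraries. The consensus peaks had a median width of 369 bases, and the 38441 on chromosomes lay nearest to 14241 genes. Coordinates are GRCm38/mm10.

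Libraries of 1 group resembled each other more than those of other groups. Across peaks, mean r was 0.979 within anergic, 0.983 within naive, 0.981 within Teff and 0.978 within Treg libraries. Between groups it was 0.921 for anergic with Treg, 0.919 for Teff with Treg, 0.901 for anergic with Teff, 0.881 for naive with Teff, 0.869 for naive with Treg and 0.773 for anergic with naive. These correlations run across peaks, which are not independent replicates. The first component held 73.6% of the variance and placed naive libraries at -137 ± 3.5 (SD, n = 2), Teff at -9.1 ± 9.5, Treg at 21.6 ± 5.2 and anergic at 78.8 ± 1.5 (n = 3 each). Component 2 (14.5%) placed Teff at -51.3 ± 9.2 and the other groups between 11.8 and 25.1.

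**Figure D1:**
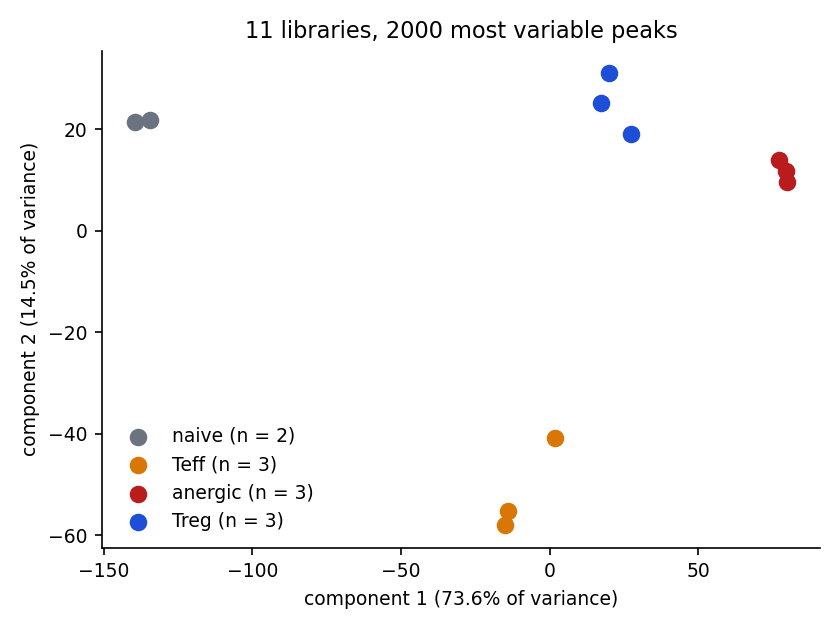
Position of each of the 11 libraries (points, coloured by group) on both principal components of the 2000 most variable peaks. Naive libraries lie at a mean of -137 and anergic libraries at 78.8 on the first component.

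The comparison of anergic with Teff cells asks how unresponsive cells differ from other antigen-experienced cells. Nt5e, which encodes the sort marker CD73, rose at 4 of 5 peaks in anergic cells and fell at 1, with the most certain rise at an intronic peak 5.03 kb from its start site (chromosome 9, 88332304 to 88332968), from 134 ± 26.6 in Teff to 592 ± 53 (SD, n = 3 each; log2 fold change 2.15 ± 0.22, adjusted p = 1.65e-07). Izumo1r, which encodes the folate receptor FR4, rose at 4 of 7 peaks, with 1.08 ± 0.17 at an intronic peak (chromosome 9, 14901835 to 14904367). Nrp1 rose at 1 of 3 peaks (0.91 ± 0.14) and Cd44, an adhesion receptor of experienced T cells, rose at 5 and fell at 1 of 16, with 2.11 ± 0.16 at a peak 55.4 kb away. Foxp3, the lineage factor of Treg cells, rose at its only peak, in an intron 3.57 kb from the start site (chromosome X, 7583720 to 7584393), from 31.1 ± 27.9 to 131 ± 46.4 (2.33 ± 0.41, adjusted p = 0.000106, and 1.95 to 3.0 over the alternatives), against 1330 ± 244 in Treg. Il2ra, the CD25 gene, fell at 5 and rose at 1 of 13 peaks (-1.23 ± 0.18 at an intronic peak). No Cd4 peak of 4 passed.

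Bcl2l11 changed both ways in anergic cells, with 5 of 14 peaks higher and 5 lower than in Teff. The largest fall was in an intron 25.8 kb from the start site (chromosome 2, 128152779 to 128154012), from 1550 ± 290 to 331 ± 85 (n = 3 each; -2.24 ± 0.17, adjusted p = 2.08e-09). That peak stood at 1440 ± 65.9 in naive and 1130 ± 66.8 in Treg. Further Bcl2l11 peaks, chosen after their values were seen, include the 5' UTR peak (128125371 to 128126707), which fell from 2540 ± 214 to 1470 ± 164 (-0.80, adjusted p = 3.69e-06). A Bcl2l11 peak 8.21 kb upstream of the start site (128117601 to 128118049) rose from 130 ± 1.05 to 465 ± 72.3 (1.81), and the upstream peak at 128092095 to 128092476 rose by 2.27. Batf rose at 3 of 10 peaks and fell at 1, whose change was the most certain (chromosome 12, 85660919 to 85661243, 25.6 kb from the start site; 290 ± 30.5 in Teff, 127 ± 41.5 in anergic; -1.23 ± 0.23, adjusted p = 0.000262). The risen Batf peaks, also chosen after their values were seen, changed by 1.64, 1.26 and 0.62, and the Batf 5' UTR peak did not pass (0.22, adjusted p = 0.252).

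**Figure D2:**
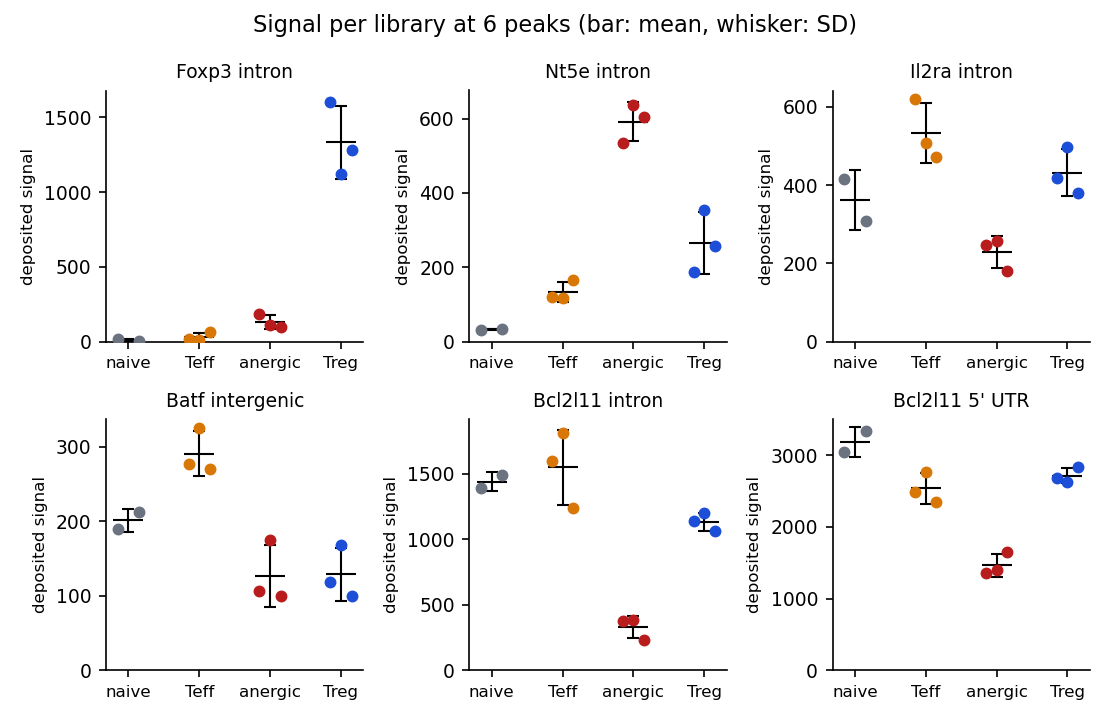
Deposited signal of each library (points) at 6 peaks, with the group mean (bar) and SD (whisker), n = 2 for naive and 3 for the other groups. At the Bcl2l11 intron the anergic mean is 331 and the Teff mean 1550, and at the Foxp3 intron the means are 131 in anergic and 1330 in Treg.

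Over all peaks, 12612 of 38493 differed between anergic and Teff cells, 6133 higher and 6479 lower in anergic, and 6796 by at least 2-fold. Of these calls, 97.8% were also made by edgeR. The largest rises were nearest to Dhx35 (5.07 ± 0.3, 339.0 kb away), Tnr (4.67 ± 0.28), the integrin gene Itgav (4.4 ± 0.3, with 8 of 8 peaks higher), Nampt (4.27 ± 0.44) and Lrrfip2 (4.26 ± 0.3). The largest falls were nearest to Gramd3 (-4.71 ± 0.41, with 13 of 15 peaks lower), Scn8a (-4.42 ± 0.62, and -5.66 to -3.43 over the alternatives), Bst1 (-4.07 ± 0.26), Bcas3 (-4.04 ± 0.27) and Fxyd3 (-3.72 ± 0.3). Groups did not overlap at these peaks.

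**Figure D3:**
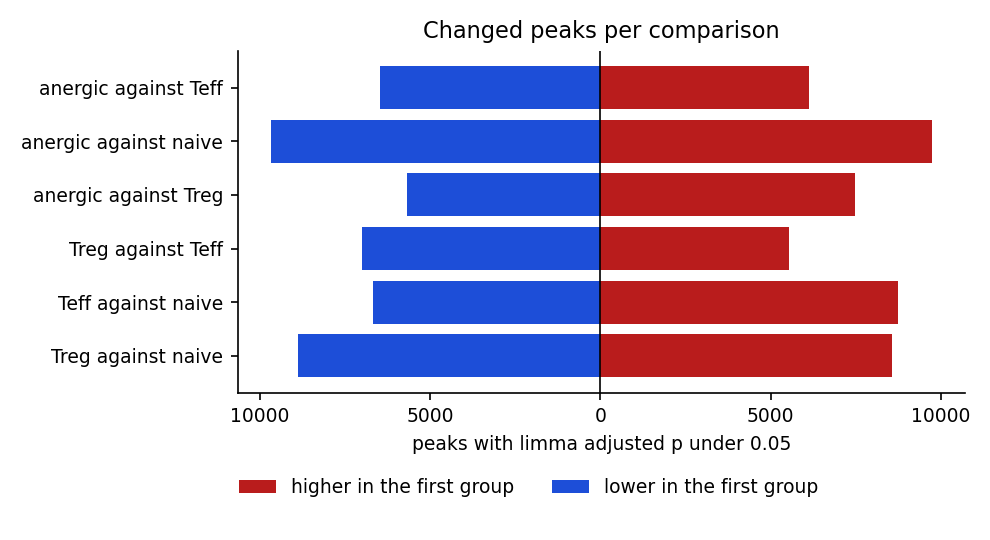
Number of peaks with a limma adjusted p under 0.05 in each comparison, higher (right) or lower (left) in the group named before "against". Anergic against naive has 19420 and Treg against Teff 12533.

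Genes of inhibitory receptors and exhaustion regulators were more accessible in anergic cells, with 103 of 172 peaks higher and 10 lower than in Teff (107 and 14 adjusted over the list alone; median log2 fold change 0.84, fry adjusted p = 2.14e-06, and 0.0194 with an estimated correlation). Il10, an anti-inflammatory cytokine, rose at 11 of 13 peaks, with 3.25 ± 0.23 at a peak 18.8 kb away (chromosome 1, 131038041 to 131039169). Ctla4, an inhibitory receptor, rose at 17 of 21 (3.0 ± 0.22), and Tox2 rose at 5 of 7, including its 5' UTR (1.23 ± 0.1). The Treg signature rose at 77 of 180 peaks and fell at 23 (80 and 24 adjusted over the list alone; median 0.38, adjusted p = 9.95e-06, and 0.0496 with an estimated correlation), with Ikzf2 (2.13 ± 0.14) and Cd83 (2.89 ± 0.2) among the risen. Genes of follicular helper cells (Tfh) rose at 91 of 167 peaks and fell at 12 (98 and 17 adjusted over the list alone; median 0.8, fry adjusted p = 2.23e-05, adjusted p = 0.0568 with an estimated correlation). Tnfsf8, a TNF family ligand, rose at 20 of 21 peaks (2.81 ± 0.16), and Angptl2 rose at 7 of 7 (2.22 ± 0.17).

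The Th1 and cytotoxic list fell at 69 of 135 peaks in anergic over Teff cells and rose at 19 (72 and 20 adjusted over the list alone; median -0.66, adjusted p = 0.103 with an estimated correlation). Tbx21, the Th1 lineage factor, fell at 4 and rose at 2 of 11 peaks, with -2.84 ± 0.24 at a peak 8.34 kb away, while the chemokine gene Ccl3 (-2.66 ± 0.23) and Hopx (-1.61 ± 0.15) fell as well. Th2 genes fell at 24 of 64 peaks and rose at 14 (median -0.36, adjusted p = 0.29 with an estimated correlation), with Il13 falling at 5 of 7 (-2.83 ± 0.24) and Areg rising (2.45 ± 0.21). Th17 genes fell at 20 of 48 and rose at 9 (median -0.41, adjusted p = 0.108 with an estimated correlation). By gene the tally went the other way, with 4 of 8 Th17 genes having only higher and 1 only lower peaks, since 13 of the fallen peaks were of Il21r and 6 of Rora. Rora (-1.51 ± 0.14) and Il21r (-2.98 ± 0.26) fell and Ahr rose (2.52 ± 0.34). Naive and quiescence genes fell at 107 of 390 peaks and rose at 48 (median -0.25, adjusted p = 0.329 with an estimated correlation), with Lef1 falling at 19 of 49 (-2.42 ± 0.17), Satb1 at 19 of 21 (-1.05 ± 0.1) and Ets1 rising at 7 (1.81 ± 0.14).

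Cytokines and TNF family ligands rose at 54 of 129 peaks and fell at 28 (median 0.28, adjusted p = 0.155 with an estimated correlation). The risen peaks include those of Il10 and Tnfsf8, already counted under other lists. By gene, 8 of 22 cytokine list genes had only higher and 5 only lower peaks. The adenosine and folate receptor pathway rose at 14 of 33 and fell at 3 (median 0.34, adjusted p = 0.0959 with an estimated correlation), with Dpp4 (1.25 ± 0.19) and Adora2a (0.72 ± 0.11) among the risen. That list holds Nt5e (4 peaks higher and 1 lower) and Izumo1r (4 higher and 0 lower), the genes of sort markers CD73 and FR4. Its rise is therefore not independent of the sort. AP-1, BATF and IRF factors rose at 29 of 131 and fell at 22 (median 0.11, adjusted p = 0.506 with an estimated correlation), with Irf4 (2.43 ± 0.21) and Nfil3 (2.99 ± 0.28) higher and Irf8 (-2.4 ± 0.28) lower. By gene, 3 of these 19 had only higher and 7 only lower peaks. NR4A, EGR and NFAT factors rose at 25 of 89 and fell at 16 (median 0.08, adjusted p = 0.506 with an estimated correlation). Among them Egr3 rose (2.7 ± 0.36) and Nr4a1 (-0.86 ± 0.11) and Nfatc1 (-1.45 ± 0.19) fell. The BCL2 family and cell death list rose at 28 of 133 and fell at 24 (median 0.05, adjusted p = 0.639 with an estimated correlation), with Fasl lower (-2.1 ± 0.24). The sort markers rose at 16 of 56 and fell at 8 (median 0.09, adjusted p = 0.506 with an estimated correlation). The fry calls of these last 4 lists were lost under scaling by total reads in peaks. Anergy and negative TCR regulators did not pass (47 higher and 39 lower of 220; median -0.01, mean 0.07, adjusted p = 0.288), although Ndrg1 rose (2.56 ± 0.18) and Nedd4 fell (-1.79 ± 0.15). Migration and tissue residency did not pass either (46 higher, 59 lower of 210; median -0.15, adjusted p = 0.129), with Itga4 higher (2.56 ± 0.16) and Selplg lower (-2.11 ± 0.16).

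Markers of other cell types were measured beside these groups. B cell markers rose at 13 of 31 peaks and fell at 1 (median 0.5, adjusted p = 0.0738 with an estimated correlation), including Cd74 (1.31 ± 0.14), Ly86 (3.25 ± 0.37) and Pou2af1 (2.47 ± 0.16), which is also on the Tfh list. CD8, NK and innate-like T markers fell at 19 of 29 and rose at 1 (median -2.04, adjusted p = 0.108 with an estimated correlation). Zbtb16, a factor of innate-like T cells, fell at 13 of 13 peaks, with -2.96 ± 0.3 at an intronic peak (chromosome 9, 48803443 to 48804843; 1220 ± 228 in Teff, 157 ± 32.5 in anergic). Xcl1 (-3.34 ± 0.4) and Klrb1c (-1.46 ± 0.17) fell too. Erythroid and platelet markers rose at 5 of 10 peaks and fell at 1 (median 0.35, adjusted p = 0.256 with an estimated correlation), with Alas2 at 1.98 ± 0.31. Myeloid and dendritic markers (4 higher and 4 lower of 33; median 0.01, mean -0.05, adjusted p = 0.983) and housekeeping controls (4 higher and 7 lower of 66; median 0.02, mean -0.07, adjusted p = 0.361) did not pass. Cebpa rose (1.88 ± 0.14) and Actb (-0.95 ± 0.26) and Ppia (-0.69 ± 0.17) each fell at a distal peak.

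**Figure D4:**
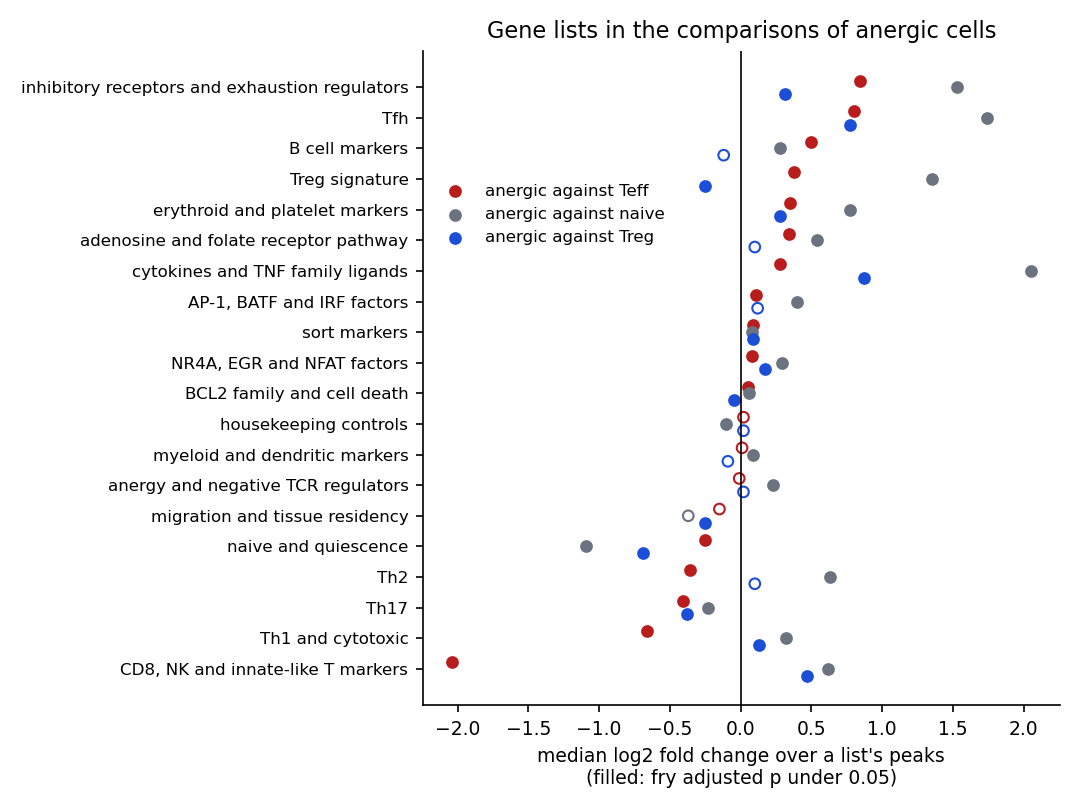
Median log2 fold change over the peaks of each of the 20 gene lists in the 3 comparisons of anergic cells; filled points have a fry adjusted p under 0.05. The inhibitory receptor list has medians of 0.84, 1.53 and 0.31 against Teff, naive and Treg.

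Over all 6 comparisons, 93 of 120 list tests passed by fry, 61 by camera with its preset correlation and 17 with an estimated correlation. Those 17 are the Treg signature in each comparison except anergic against Treg, the cytokine list in the comparisons of anergic with naive, anergic with Treg and Teff with naive, and the inhibitory receptor list in anergic against Teff and in anergic and Treg against naive. They also include Th2 genes in Teff and Treg against naive, naive and quiescence genes in anergic against Treg and Teff against naive, Tfh genes in anergic against naive and the adenosine pathway in Treg against naive.

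Distal peaks that rose in anergic over Teff cells held the AP-1 motif, bound by JUN, FOS and BATF, in 32.2% of cases against 10.8% of unchanged peaks (odds ratio 2.98, 2.74 to 3.23, adjusted p = 8.14e-146). The BATF-IRF composite motif was in 2.73% against 0.377% (odds ratio 4.55, 3.3 to 6.27, adjusted p = 1.1e-19). The composite patterns contain the AP-1 pattern, and the regression did not adjust for it. In each comparison the composite odds ratio therefore includes that of AP-1 and is not separate evidence. NFAT (2.48), NF-kB (1.86) and NR4A (1.64) motifs also had raised odds. Peaks that fell had raised odds of ROR (2.81), T-box (2.04), RUNX (1.75), ETS (1.65) and GATA (1.35) motifs and lower odds of AP-1 (0.684). Of 192 motif tests over the comparisons, 137 passed, 53 with an odds ratio above 1. Changed peaks were less often at promoters: 16.5% of risen and 16% of fallen peaks against 41.5% of unchanged peaks (odds ratios 0.278 and 0.268).

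**Figure D5:**
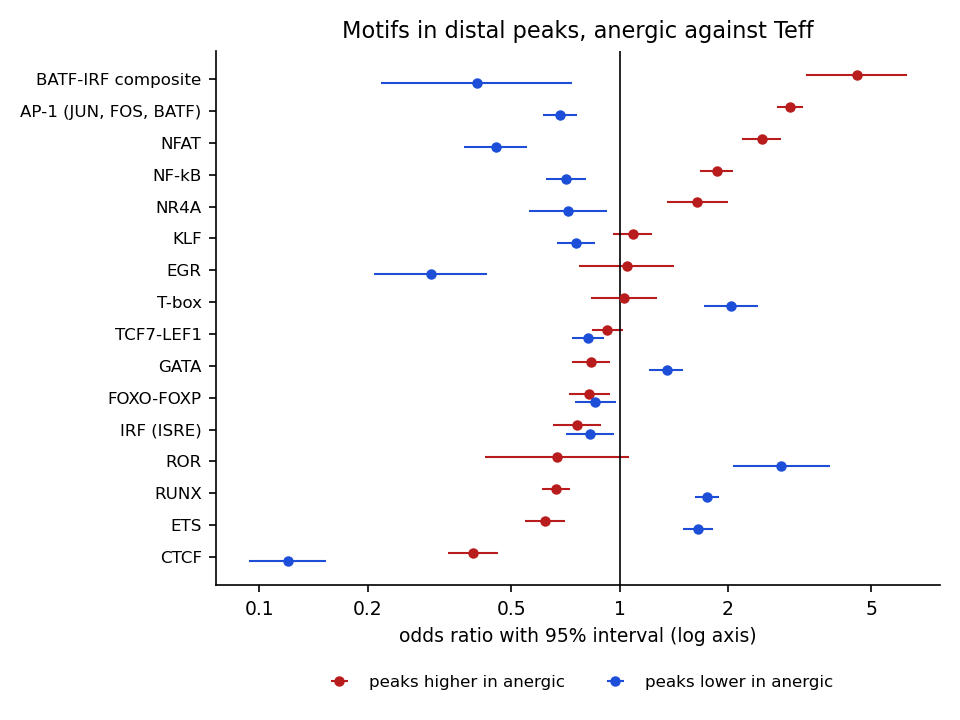
Odds ratio (log axis) with its 95% interval for 16 motifs in distal peaks higher or lower in anergic than in Teff cells. The BATF-IRF composite, whose patterns contain that of AP-1, has an odds ratio of 4.55 in higher peaks, and ROR has 2.81 in lower peaks.

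The comparison of anergic with Treg cells asks what separates both kinds of tolerant cell. Foxp3 was lower in anergic cells (-3.37 ± 0.41, adjusted p = 2.06e-06), and Il2ra fell at 10 of 13 peaks, with -3.68 ± 0.28 at a peak 6.67 kb away (chromosome 2, 11635902 to 11636351; 416 ± 83.3 in Treg, 32.8 ± 12.9 in anergic; n = 3 each). Lrrc32, which presents TGF-beta on Treg cells, fell at 11 of 11 peaks (-3.07 ± 0.23). Bcl2l11 fell at 7 and rose at 1 of 14 peaks, with -1.81 ± 0.17 at the intronic peak 25.8 kb from its start. Batf rose at 4 of 10 peaks (1.23 ± 0.3 at chromosome 12, 85712568 to 85712824). Nt5e (1.19 ± 0.22, with 1 other peak lower), Cd44 (1.29 ± 0.16), Cd4 (0.85 ± 0.14) and Izumo1r (0.97 ± 0.13, with 1 other peak lower) rose. No Nrp1 peak of 3 passed (-0.52 ± 0.23, adjusted p = 0.0803).

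Of the tested peaks, 13142 differed between anergic and Treg cells, 7462 higher and 5680 lower, and 91.8% of the calls were shared with edgeR. Scaling by total reads in peaks gave 5078 higher and 7571 lower, so the balance of directions depends on the scaling. Il21, a cytokine of follicular helper cells, rose the most (4.78 ± 0.38, range 4.26 to 5.38 over the alternatives, with 7 of 7 peaks higher), and other large rises were nearest to Chn1os3 (4.32 ± 0.31), Ubap2 (3.94 ± 0.28) and Olfr157 (3.68 ± 0.33). Among the largest falls were peaks nearest to Stat3 (-4.1 ± 0.58, and -4.88 to -2.91 over the alternatives), Manba (-3.77 ± 0.27), Nin (-3.75 ± 0.45, range -4.4 to -3.02), Il2ra and Eif4e3 (-3.54 ± 0.3).

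Cytokines and TNF family ligands rose at 75 of 129 peaks in anergic over Treg cells and fell at 7 (78 and 8 adjusted over the list alone; median 0.87, fry adjusted p = 4.02e-06, and 0.0194 with an estimated correlation), with Cd40lg at 1.97 ± 0.2 and Il10 at 1.89 ± 0.19. Tfh genes rose at 92 of 167 and fell at 14 (median 0.77, adjusted p = 0.0661 with an estimated correlation), including Pou2af1 (2.93 ± 0.16) and Tox2 (1.18 ± 0.1). Inhibitory receptors rose at 60 of 172 and fell at 15 (median 0.31, adjusted p = 0.114 with an estimated correlation), with Tox at 2.65 ± 0.23. Naive and quiescence genes fell at 206 of 390 peaks and rose at 19 (median -0.69, fry adjusted p = 1.98e-05, and 0.0348 with an estimated correlation), among them Bach2 at 37 of 51 (-2.35 ± 0.17), Lef1 at 31 of 49 (-2.58 ± 0.17) and Klf2 at 10 of 16 (-2.79 ± 0.2). The Treg signature fell at 62 of 180 and rose at 23 (median -0.25, adjusted p = 0.0677 with an estimated correlation), with Gpr83 at -1.62 ± 0.14. BCL2 family and cell death genes fell at 30 of 133 and rose at 16 (median -0.05, adjusted p = 0.122 with an estimated correlation), including Tnfrsf10b (-1.28 ± 0.17) and Mcl1 (-0.72 ± 0.11). Th17 genes fell at 19 of 48 and rose at 10 (median -0.38, adjusted p = 0.133 with an estimated correlation), while 3 of 8 Th17 genes had only higher and 0 only lower peaks. The sort markers had a median of 0.09 but a mean of -0.43, and fry called them lower (adjusted p = 0.339 with an estimated correlation). Anergy and negative TCR regulators did not pass (54 higher and 40 lower of 220; median 0.02, mean -0.08), though Nfatc1 rose at 14 of 17 peaks (2.81 ± 0.19). Among other cell types, B cell markers did not pass (median -0.12, mean 0.11, adjusted p = 0.0742), with Cd74 lower (-1.3 ± 0.22). CD8, NK and innate-like T markers rose at 13 of 29 peaks and fell at 3 (median 0.47, fry adjusted p = 0.0393, adjusted p = 0.512 with an estimated correlation). Erythroid and platelet markers rose at 4 of 10 and fell at 1 (median 0.28, fry adjusted p = 0.000744, adjusted p = 0.196 with an estimated correlation). Under total reads in peaks the fry calls of the Th1, NR4A and CD8 lists were lost and housekeeping controls were called lower (median -0.11).

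Distal peaks higher in anergic than Treg cells had raised odds of the BATF-IRF composite (2.95), NFAT (2.37), AP-1 (2.18) and TCF7-LEF1 (1.39) motifs. Those lower had raised odds of GATA (1.4), NR4A (1.38) and ETS (1.35). Promoters made up 15.6% of fallen peaks against 36.5% of unchanged ones (odds ratio 0.321). Their share among risen peaks did not pass (35.3%, odds ratio 0.949, adjusted p = 0.0586) and was lower under 5 other settings, with odds ratios of 0.52 (loess offsets) to 0.882 (DESeq2 size factors). Under loess offsets risen and fallen peaks had similar shares (23.8% and 24.8%).

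Comparing anergic with naive cells asks what distinguishes tolerant from unexperienced cells. Cd44 rose at 10 and fell at 1 of 16 peaks, from 49.3 ± 15.7 (n = 2) to 2090 ± 102 (n = 3) at its most certain (5.42 ± 0.18, adjusted p = 9.67e-16). Nt5e rose (4.13 ± 0.25), as did Izumo1r (2.82 ± 0.2, each with 1 other peak lower), Nrp1 (1.25 ± 0.16) and Foxp3 (3.41 ± 0.45, range 2.81 to 3.87 over the alternatives, from 11.6 ± 5.44 to 131 ± 46.4). Batf rose at 6 of 10 peaks and fell at 1, with 2.86 ± 0.24 in an intron 17.0 kb from its start (chromosome 12, 85703525 to 85703940). Bcl2l11 fell at 7 and rose at 3 of 14 peaks, and its most certain change was a rise at the upstream peak at chromosome 2, 128117601 to 128118049 (3.63 ± 0.28). Il2ra fell at 7 and rose at 2 of 13 (-2.79 ± 0.34). Cd4 rose at 1 of 4 peaks (1.47 ± 0.4), a call lost without naive replicate 1 (1.18, adjusted p = 0.0636).

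In all, 19420 peaks differed between anergic and naive cells, 9742 higher and 9678 lower, and edgeR made 98.5% of these calls. Among the largest rises were peaks nearest to Ksr2 (7.87 ± 0.38, range 6.25 to 8.91), Lrrfip2 (7.72 ± 0.34, 5.98 to 8.35), Supt3 (7.69 ± 0.26, 6.32 to 8.1) and Nampt (7.59 ± 0.5). Naive means at those peaks were 1.97 to 7.7, a few reads, so these folds depend on the pseudocount, and Nampt went from 6.02 to 9.16 by which naive library was left out. Falls were largest near Slc25a33 (-5.03 ± 0.3), Adamts14 (-4.51 ± 0.31), Uvrag (-4.15 ± 0.27), Polr1a (-4.03 ± 0.49, range -4.74 to -3.33) and Zfp800 (-4.0 ± 0.44).

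Inhibitory receptors rose at 119 of 172 peaks against naive and fell at 18 (121 and 20 adjusted over the list alone; median 1.53, fry adjusted p = 1.68e-07, and 0.0194 with an estimated correlation), with Il10 (7.44 ± 0.21, range 6.66 to 7.92), Ctla4 (6.08 ± 0.24, 5.37 to 6.23) and Tigit at 11 of 11 peaks (5.89 ± 0.24, 5.27 to 6.22). Cytokines rose at 86 of 129 and fell at 19 (median 2.05; 0.0194 with an estimated correlation), with Tnfsf8 at 6.91 ± 0.17. Tfh genes rose at 121 of 167 and fell at 7 (median 1.74; 0.0418 with an estimated correlation), with Cxcr5 at 2.78 ± 0.13. The Treg signature rose at 119 of 180 and fell at 19 (median 1.35; 0.0194 with an estimated correlation), with Ikzf2 higher at 17 of 17 peaks (5.72 ± 0.15). Naive and quiescence genes fell at 254 of 390 and rose at 52 (median -1.09, adjusted p = 0.0577 with an estimated correlation), with Lef1 lower at 44 of 49 (-3.94 ± 0.19) and Ets1 rising at 14 (4.43 ± 0.16). AP-1, BATF and IRF factors rose at 61 of 131 and fell at 19 (median 0.4, adjusted p = 0.0705 with an estimated correlation), including Bhlhe40 (2.55 ± 0.11) and Maf (4.02 ± 0.22). Anergy and negative TCR regulators rose at 84 of 220 and fell at 41 (median 0.23, adjusted p = 0.232 with an estimated correlation), including Ptpn22 (5.31 ± 0.25, range 4.62 to 5.77). Th17 genes were called higher by fry with a mean of 0.92 but a median of -0.23 (adjusted p = 0.679 with an estimated correlation). Migration and tissue residency did not pass (57 higher, 84 lower of 210; median -0.37, mean 0.13). The CD8 gene Cd8b1 fell (-2.62 ± 0.25) while the CD8, NK and innate-like list rose at 13 of 29 and fell at 5 (median 0.62, adjusted p = 0.53 with an estimated correlation). By gene, 2 of 6 on that list had only higher and 3 only lower peaks. Fry also called higher B cell markers (11 higher and 5 lower of 31; median 0.28, adjusted p = 0.506 with an estimated correlation), myeloid and dendritic markers (10 and 6 of 33, median 0.09, adjusted p = 0.649 with an estimated correlation) and erythroid and platelet markers (5 and 1 of 10, median 0.77, adjusted p = 0.425 with an estimated correlation). Housekeeping controls were called lower (median -0.1, adjusted p = 0.639 with an estimated correlation), a call lost under total reads.

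Motifs with raised odds in the distal peaks gained by anergic over naive cells were the BATF-IRF composite (5.09), AP-1 (2.83), NF-kB (2.11), NFAT (1.88), NR4A (1.5) and T-box (1.42). Lost peaks had raised odds of ETS (1.51), TCF7-LEF1 (1.35), RUNX (1.3) and GATA (1.17). Promoters were 19.8% of risen and 22.1% of fallen peaks, against 45.7% of unchanged peaks.

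Treg against Teff cells sets the regulatory against the conventional experienced population. Foxp3 rose the most (5.7 ± 0.41, adjusted p = 1.68e-09, range 5.3 to 6.49 over the alternatives; 31.1 ± 27.9 in Teff, 1330 ± 244 in Treg; n = 3 each). Teff replicate 3 read 63.3 at the Foxp3 peak and the others 15.9 and 14. Il2ra rose at 9 of 13 peaks (3.1 ± 0.3). Bcl2l11 rose at 8 and fell at 1 of 14 peaks, with 2.25 ± 0.23 at the upstream peak at chromosome 2, 128092095 to 128092476. Batf fell at 1 of 10 peaks (-1.2 ± 0.23). Nrp1 (0.81 ± 0.14) and Nt5e (0.95 ± 0.22) rose, and Cd4 fell at 1 of 4 (-0.81 ± 0.14). Cd44 rose at 3 and fell at 5 of 16 (-0.99 ± 0.16), and Izumo1r rose at 5 and fell at 1 of 7 (-0.98 ± 0.13 at its most certain). In all, 12533 peaks differed, 5535 higher and 6998 lower in Treg, and 90.3% of the calls were shared with edgeR. Total reads in peaks gave 6935 higher and 5163 lower. After Foxp3, the largest rises that met the naming rule were nearest to Ppm1b (5.21 ± 0.35, range 4.85 to 5.79), Lrrc32 (4.93 ± 0.36, range 4.5 to 5.65), Nup35 (4.03 ± 0.33) and Emsy (3.88 ± 0.27). The largest falls were nearest to Nnmt (-4.59 ± 0.35), Zbtb16 (-4.47 ± 0.3), Il13 (-4.44 ± 0.24), Eif3h (-4.38 ± 0.28) and Pgap1 (-4.32 ± 0.26).

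The Treg signature rose at 112 of 180 peaks in Treg over Teff and fell at 10 (118 and 16 adjusted over the list alone; median 0.87, fry adjusted p = 8.88e-07, and 0.0175 with an estimated correlation), with Gpr83 at 2.0 ± 0.14. Inhibitory receptors rose at 77 of 172 and fell at 21 (median 0.5, adjusted p = 0.0538 with an estimated correlation), including Tox (3.43 ± 0.18) and Pdcd1 (2.2 ± 0.25). Naive and quiescence genes rose at 168 of 390 and fell at 29 (median 0.47, adjusted p = 0.0636 with an estimated correlation), with Foxp1 higher at 40 of 56 peaks (1.74 ± 0.13), Ccr7 (1.23 ± 0.13) and Foxo1 (1.51 ± 0.16). Th1 and cytotoxic genes fell at 77 of 135 and rose at 11 (median -0.7, adjusted p = 0.0635 with an estimated correlation), including Cxcr6 (-3.03 ± 0.18), Il12rb2 (-3.7 ± 0.24) and Stat4 (-2.57 ± 0.18). Cytokines fell at 54 of 129 and rose at 29 (median -0.37, adjusted p = 0.2 with an estimated correlation), with Ifng at -3.86 ± 0.28 (range -4.46 to -3.51). Th2 genes were called lower by fry with a mean of -0.28 and a median of 0.04 (adjusted p = 0.976 with an estimated correlation; call lost under total reads), with Il4 at -3.1 ± 0.3. NR4A, EGR and NFAT factors were called lower (median -0.1, adjusted p = 0.614 with an estimated correlation), with 4 of 10 genes having only higher and 2 only lower peaks, and the call turned under total reads (median 0, adjusted p = 0.948). Total reads also added fry calls for the AP-1 and migration lists. Among other cell types, CD8, NK and innate-like T markers fell at 20 of 29 peaks and rose at 2 (median -1.67, fry adjusted p = 3.4e-05, adjusted p = 0.0912 with an estimated correlation). B cell markers rose at 14 of 31 and fell at 3 (median 0.44, fry adjusted p = 0.000356, adjusted p = 0.104 with an estimated correlation). Distal peaks higher in Treg had raised odds of NR4A (2.55), NF-kB (1.88), BATF-IRF composite (1.76) and AP-1 (1.48) motifs, and lower ones of ROR (3.91), T-box (2.27), RUNX (1.93) and ETS (1.44). Promoters were 13.7% of risen and 31.8% of fallen peaks, against 37.7% of unchanged ones. Under loess offsets they were 24.2% of risen and 21.9% of fallen peaks, so the contrast between risen and fallen peaks depends on the scaling.

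Teff against naive cells compares CD44 high with CD44 low conventional cells. Changes within cells and differences in the cell types that each gate held were not separated. Cd44 rose (3.3 ± 0.18, adjusted p = 7.36e-12; 49.3 ± 15.7, n = 2, in naive and 485 ± 59.7, n = 3, in Teff). Nt5e (1.98 ± 0.25), Izumo1r (1.73 ± 0.2, with 2 other peaks lower) and Batf at 6 of 10 peaks (2.45 ± 0.24) rose. Bcl2l11 fell at 7 and rose at 2 of 14 (-2.13 ± 0.32), and Il2ra rose at 2 and fell at 4 of 13 (0.9 ± 0.19). No peak of Cd4, Nrp1 or Foxp3 passed (Foxp3 1.08 ± 0.45, adjusted p = 0.0625, range 0.41 to 1.54 over 18 alternatives, of which 3 passed). Of the tested peaks, 15423 differed, 8744 higher and 6679 lower, and edgeR made 98.4% of these calls. The share higher, 56.7%, rose when either naive library was left out, and was 58.4 to 58.6% without 1 Teff library. With both naive libraries kept, it ran from 52.7% in a fit of only the groups compared to 62.7% under total reads in peaks. The balance of directions therefore depends on the processing as well as on the libraries. The largest rises were nearest to Gas7 (7.27 ± 0.38, from a naive mean of 2.42 ± 2.33, and 5.52 to 8.03 over the alternatives), Ppp4r2 (6.87 ± 0.32, 5.69 to 7.25), Phf21a (6.62 ± 0.32, 5.71 to 6.87), Il13 (6.55 ± 0.27, 5.86 to 7.27) and Icam2 (6.39 ± 0.27), and the largest falls nearest to Zfp800 (-3.81 ± 0.44), Slc25a33 (-3.72 ± 0.3), Alg14 (-3.56 ± 0.4), Hlcs (-3.43 ± 0.39) and Eif4e3 (-3.4 ± 0.33).

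Cytokines rose at 73 of 129 peaks in Teff over naive cells and fell at 6 (75 and 7 adjusted over the list alone; median 0.96, fry adjusted p = 6.28e-07, and 0.0194 with an estimated correlation). Th2 genes rose at 34 of 64 and fell at 9 (median 0.79; 0.0383 with an estimated correlation), including Il4 (4.84 ± 0.34, range 4.28 to 5.64). Th1 and cytotoxic genes rose at 79 of 135 and fell at 13 (median 0.86, adjusted p = 0.0661 with an estimated correlation), with Tbx21 higher at 10 of 11 (5.3 ± 0.24) and Stat4 (4.27 ± 0.2). Th17 genes rose at 23 of 48 and fell at 6 (median 0.49, adjusted p = 0.0873 with an estimated correlation), with Rora (5.04 ± 0.18) and Il17a (5.06 ± 0.55, but 3.5 without naive replicate 1 and 6.62 without naive replicate 2). The Treg signature rose at 103 of 180 and fell at 18 (median 0.92; 0.0194 with an estimated correlation), with Il2rb higher at 5 of 5 (2.21 ± 0.11). Naive and quiescence genes fell at 218 of 390 and rose at 28 (median -0.83; 0.0496 with an estimated correlation), with Lef1 lower at 40 of 49 (-2.48 ± 0.19). Innate-like markers rose at 18 of 29 and fell at 3 (median 2.18, adjusted p = 0.156 with an estimated correlation), with Zbtb16 higher at 12 of 13 (5.48 ± 0.34, range 4.88 to 5.63). Myeloid and dendritic markers were called higher by fry (8 higher and 4 lower of 33; median 0.18, adjusted p = 0.541 with an estimated correlation). Migration and tissue residency did not pass (median -0.19, mean 0.17). Distal peaks gained had raised odds of BATF-IRF composite (3.02), AP-1 (2.32), T-box (2.31), ROR (2.31), NF-kB (2.02), NFAT (1.27) and RUNX (1.13) motifs, and those lost of TCF7-LEF1 (1.61) and ETS (1.18). Promoters were 18% of risen and 24.2% of fallen peaks, against 41.6% of unchanged ones.

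Treg against naive cells completes the set. Foxp3 (6.78 ± 0.45, adjusted p = 9.83e-11, range 6.11 to 7.24 over the alternatives) and Lrrc32 (6.94 ± 0.4, range 6.19 to 7.71) rose, from naive means of 11.6 ± 5.44 and 9.58 ± 3.69 (n = 2) to 1330 ± 244 and 1270 ± 161 (n = 3). Cd44 (4.28 ± 0.18, with 3 of 16 peaks lower), Nt5e (2.93 ± 0.25), Izumo1r (2.51 ± 0.2, with 1 of 7 lower), Nrp1 at 3 of 3 peaks (1.15 ± 0.16) and Il2ra at 8 of 13 (2.25 ± 0.19, with 1 lower) rose. Batf rose at 5 and fell at 1 of 10 (2.49 ± 0.24), Bcl2l11 rose at 3 and fell at 2 of 14 (2.51 ± 0.25), and Cd4 fell at 2 of 4 (-1.07 ± 0.15). In all, 17435 peaks differed, 8568 higher and 8867 lower, with 91.8% of the calls shared with edgeR. Total reads in peaks gave 10709 higher and 5721 lower and moved the median of all peaks from -0.04 to 0.12. The share of higher peaks also rose when either naive library was left out. Other large rises were nearest to Supt3 (6.62 ± 0.26, range 5.26 to 7.03), Nampt (6.6 ± 0.5, 5.03 to 8.17) and Ksr2 (6.59 ± 0.38, 4.99 to 7.63), and falls nearest to Zfp800 (-4.77 ± 0.44), Mgme1 (-4.31 ± 0.49, range -4.62 to -3.72), Tnks (-4.24 ± 0.29), Hlf (-4.19 ± 0.49, range -5.01 to -3.53) and Dync1li2 (-4.06 ± 0.23).

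The Treg signature rose at 151 of 180 peaks in Treg over naive cells and fell at 4 (151 and 6 adjusted over the list alone; median 1.97, fry adjusted p = 6.37e-08, and 0.00672 with an estimated correlation), with Ikzf2 higher at 17 of 17 (5.2 ± 0.15) and Cd83 (6.06 ± 0.22, range 5.2 to 6.29). Inhibitory receptors rose at 115 of 172 and fell at 17 (median 1.21; 0.0194 with an estimated correlation), with Ctla4 higher at 19 of 21 (3.34 ± 0.16). The adenosine and folate receptor pathway rose at 16 of 33 and fell at 3 (median 0.7; 0.0494 with an estimated correlation), with Adora2a at 1.69 ± 0.12. Th2 genes rose at 32 of 64 and fell at 6 (median 0.49; 0.0383 with an estimated correlation), with Areg at 3.0 ± 0.24. BCL2 family genes rose at 39 of 133 and fell at 20 (median 0.1, adjusted p = 0.122 with an estimated correlation), including Pmaip1 (3.15 ± 0.26) and Bcl2l1 (2.14 ± 0.18). Naive and quiescence genes fell at 128 of 390 and rose at 54 (median -0.3, adjusted p = 0.403 with an estimated correlation), a call lost under total reads, with Foxp1 rising at 15 and falling at 7 of 56. Migration and tissue residency was called higher with a mean of 0.29 and a median of -0.04 (adjusted p = 0.933 with an estimated correlation), with Itgb1 at 5.48 ± 0.18 (range 4.86 to 5.69). Among other cell types, fry called higher B cell markers (11 higher and 4 lower of 31; median 0.15, adjusted p = 0.468 with an estimated correlation) and myeloid and dendritic markers (10 and 3 of 33, median 0.11, adjusted p = 0.512 with an estimated correlation). Gained distal peaks had raised odds of BATF-IRF composite (3.95), AP-1 (2.68), NF-kB (2.54), NR4A (1.98), NFAT (1.5) and T-box (1.33) motifs, and lost ones of TCF7-LEF1 (1.81), RUNX (1.53) and ETS (1.42). Promoters were 16.6% of risen peaks against 36.8% of unchanged ones. Their share of 40.7% among fallen peaks was higher (odds ratio 1.18, adjusted p = 3.48e-10), and this turned to 0.98 within 3000 bases, 0.83 under total reads and 0.565 under loess offsets. It did not pass by Fisher's test with DESeq2 size factors (1.04, adjusted p = 0.166) or TMM factors (1.03, adjusted p = 0.273), so the higher share held under no alternative.

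Changes of anergic and Treg cells over Teff overlapped. Both rose at 2766 peaks, against 882 for independent lists, and both fell at 3232, against 1178. They went opposite ways at 620 peaks. Across peaks r was 0.59 with a covariance of 0.414. In 20 simulations of unchanged groups, with simulated Teff libraries as shared controls, mean r was 0.498 and the covariance 0.031. The simulations gave 0 shared calls, but no change was planted in them, so that count is no yardstick for the shared calls. For anergic and Teff cells over naive, both rose at 6834 peaks (2213 for independent lists) and both fell at 5227 (1679), with 269 opposite. There r was 0.83 with a covariance of 1.498, against 0.6 and 0.046 in simulations. The controls, 3 Teff and 2 naive libraries, were not split between the comparisons, since 1 part would hold fewer than 2, so part of the excess may come from the shared controls.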

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

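The tests with edgeR, TMM factors in the limma fit, a pseudocount of 8, thinned reads, the 3 shallowest libraries left out and the promoter share under other scalings were chosen after the data were seen; the others were planned. Totals of changed peaks stayed within 1.5 times their value under each alternative except a stricter threshold: with adjusted p under 0.01 there were 8302 for anergic against Treg and 8025 for Treg against Teff, and 3849 shared changes of anergic and Treg over Teff, since fewer peaks meet a stricter threshold. Leaving out 1 library gave 10285 to 12060 peaks for anergic against Teff, 15285 to 18804 for anergic against naive, 10178 to 12992 for anergic against Treg, 9082 to 12561 for Treg against Teff, 10550 to 14165 for Teff against naive and 11990 to 16284 for Treg against naive. Without 1 naive library the spread was estimated from the other groups. Counts of lower peaks moved more than totals: without either naive library, fewer peaks were lower in Teff and in Treg than in naive. Each such fit held 1 naive library, and the cause was not tested. A block for replicate number gave 13235 for anergic against Teff, 19219 for anergic against naive, 13884 for anergic against Treg, 13211 for Treg against Teff, 15358 for Teff against naive and 17162 for Treg against naive. Residuals of libraries sharing a number had r from -0.11 to 0.16 (median 0.02, 4 of 15 pairs over 0.1). Yet 7 of 11 libraries matched best with a library of their own number. Whether numbers mark pairs therefore stays open, and the main fit did not treat them as pairs.

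Of 369 named results, each a peak in 1 comparison, 364 passed and none changed direction. Among the calls lost under 1 or more alternatives were those of Cd4 (anergic against naive), Nfe2 and Itga2b (Teff against naive) and Actb (Treg against naive). Without naive replicate 1, Nfe2 was 0.42 (adjusted p = 0.134), Itga2b 0.77 (0.152) and Actb -0.46 (0.0629), and without Teff replicate 2 Nfe2 was 0.43 (0.0611).

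Gene list calls by fry numbered 93, against 61 by camera with its preset correlation and 17 with an estimated one; both compare a list with other peaks, which fry does not. Under total reads in peaks the median of NR4A, EGR and NFAT factors in Treg against Teff became 0 (adjusted p = 0.948). With promoter peaks only, 17 further list calls were lost, and the direction of the fry test turned for 12 tests of 8 lists. Their medians over promoter peaks, which need not share the direction of that test, were as follows. Against Teff, anergic cells had 0.01 for BCL2 family and -0.11 for myeloid markers (adjusted p = 0.00109). Against naive they had 0.35 for CD8, NK and innate-like markers and 0.02 for housekeeping controls. Against Treg they had -0.11 for Th1, 0.07 for BCL2 family, -0.67 for CD8, NK and innate-like markers and 0.2 for housekeeping controls (adjusted p = 0.0356). Treg against Teff had -0.02 for Tfh (adjusted p = 0.0276), -0.16 for AP-1, BATF and IRF factors (adjusted p = 0.0116), 0.23 for NR4A, EGR and NFAT factors and -0.03 for BCL2 family. The cause was not tested.

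The odds ratio of promoters among peaks lower in Treg than naive became 0.98 within 3000 bases, 0.83 under total reads and 0.565 under loess offsets. With DESeq2 size factors (1.04) and TMM factors (1.03) it did not pass. The cause was not tested. Among motif results that passed before or under the alternative, odds ratios that crossed 1 over all peaks were KLF in anergic over Teff, higher (0.901), TCF7-LEF1 (1.02), KLF (0.903) and RUNX (1.04) in anergic over naive, higher, RUNX in anergic over Treg, lower (1.1), AP-1 in Treg over Teff, lower (1.02), and KLF in Treg over naive, higher (0.883). In the central 200 bases they were FOXO-FOXP in anergic over Teff, lower (1.06), RUNX (1.05) and FOXO-FOXP (1.01) in anergic over naive, higher, and EGR (1.27) and KLF (1.18) in Teff over naive, higher. The cause was not tested.

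Mean r of anergic with naive libraries, 0.773, was 0.759 with a prior count of 0.5, 0.942 over promoter and 0.497 over distal peaks; the cause was not tested. Thinning all libraries to 14.7 M reads gave 11478 changed peaks for anergic against Teff and 11015 for Treg against Teff, and leaving out the 3 shallowest libraries gave 11549 and 11940. At these depths and this spread, 21.1% of simulated 1.5-fold changes between anergic and Teff cells were recovered. The simulation held far fewer changed peaks than the real data, so this is not the real recovery. Depth, spread and the number of changed peaks were not tested apart.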

Other observations

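The tests on Foxp3, Zbtb16 and the Tfh and B cell lists were chosen after the results were seen; the splits of libraries were planned. Some peaks set 1 group apart from all 3 others. Anergic cells were higher than each other group at 2862 peaks and lower at 2204, Teff at 1673 and 406, naive at 3461 and 5666, and Treg at 629 and 1579. Under total reads in peaks the Treg counts were 1081 and 745 and the anergic counts 2379 and 2489. Genes named here were chosen after their values were seen. Peaks highest in anergic cells included 15 of 21 of Tnfsf8, 10 of 22 of Tox, 9 of 13 of Il10, 8 of 13 of Itgb1 and 10 of 24 of Fyn, a kinase of T cell receptor signalling. Peaks lowest in anergic cells included 18 of 51 of Bach2, 18 of 21 of Satb1, 17 of 49 of Lef1 and 15 of 56 of Foxp1, factors tied to naive or quiescent T cells, and 11 of 13 of Smad7.

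Teff cells were highest at 12 of 13 Zbtb16 peaks, 5 of 7 of Il13, 6 of 7 of P2rx7 and 8 of 21 of Smad3. Treg cells were highest at 11 of 11 peaks of Lrrc32, 9 of 11 of Dusp4, 8 of 13 of Il2ra and 5 of 8 of Cish, a suppressor of cytokine signalling. Naive cells were highest at 32 of 49 Lef1 peaks and 12 of 21 of Satb1.

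Foxp3 was more accessible in anergic than in Teff cells, although both were sorted as FOXP3 negative. The scaling or depth of the libraries was argued against: each alternative passed, with log2 fold changes from 1.95 without Teff replicate 2 to 3.0 without Teff replicate 3, which read 63.3 against 15.9 and 14 in the other Teff libraries. Carry-over of Treg cells into the anergic gate would need a share of 7.73% (5 to 11.8% by library) to give this signal, which would also lift other peaks restricted to Treg. Of 45 such peaks, 4 lay below the level this share needs in each of 3 anergic libraries, but 1 lay below 50% of it (Lrrc32, chromosome 7, 98562942 to 98563362: 20.8 ± 10.1 in anergic, 32.2 in Teff, 962 in Treg, with 74.3 needed). The 45 peaks were chosen as over 8 times higher in Treg than in Teff and in naive cells, whatever their anergic value. Some were higher in anergic than in Treg cells, such as that nearest to Nampt (1020 ± 110 against 513), and such peaks cannot test carry-over. Carry-over and accessibility within anergic cells cannot be told apart, since too few peaks lie clearly below that level.

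Zbtb16 was higher in Teff than in anergic cells at 13 of 13 peaks. Scaling or depth was argued against, as at least 12 of the 13 peaks were lower in anergic cells under each alternative. Over the 12 Zbtb16 peaks restricted to Teff the log2 fold change had an SD of 0.19 (median -2.63, -2.97 to -2.34), where 38 genes with at least 4 such peaks had a median SD of 1.12 and none a lower one. One innate-like cell type present at different shares in both gates may explain a change of the same size at each peak, but of 2 other genes of such cells Xcl1 fell by 3.34 ± 0.4 and Klrb1c by 1.46 ± 0.17, less than any of these peaks. A regulated change of Zbtb16 within Teff cells stays open and was not tested.

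Tfh genes and B cell markers were both higher in anergic than in Teff cells by fry (adjusted p = 0.0568 and adjusted p = 0.0738 with an estimated correlation). Depth was argued against, as 83 of 167 Tfh peaks were higher and 9 lower with thinned reads. The cells were sorted as CD4 T cells, a gate that should leave out single B cells. B cells or B cell doublets in the anergic gate, tested on 26 peaks of 10 B cell genes that no other list holds, gave a median of 0.26 with 9 peaks higher and 1 lower, against 0.8 for Tfh genes; of the list's 20 genes 11 had a peak and 1 is on another list. The B cell signal was not particular to the anergic gate, as the B cell list also rose in Treg over Teff (14 higher and 3 lower of 31, median 0.44). Between anergic and Treg cells it did not pass (9 higher and 6 lower, median -0.12). Tfh genes did differ there by fry (92 higher and 14 lower of 167, median 0.77). Carried B cells and a Tfh-like state cannot be told apart here, since B cell genes moved in part.

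Each comparison of 3 with 3 libraries allows 10 splits of the libraries, too few for a share under 0.05. The real split gave 12612 peaks for anergic against Teff, 13142 for anergic against Treg and 12533 for Treg against Teff, and 1 split, the real one, gave as many in each. The highest of the other splits was 0. Every other split mixes both groups in each part, so differences between the groups enter the spread and few calls can be made. That 0 is therefore no yardstick for the real counts.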
